A study of Homo sapiens with 9 samples.

How the data were processed

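RNA from 9 samples of the CHLA25 Ewing sarcoma cell line was sequenced, 3 samples in each of 3 groups. Libraries were made by the TruSeq procedure and read from one end over 50 nt, per the labels' protocols. Per the submitters' processing notes, the tools were CASAVA 1.8.2, FastQC, TopHat2 2.0.5 and Bowtie2 2.2.0 and the build was GRCh37; the program that estimated abundance is not given in the sources used here. The values, as deposited, are abundances per transcript that the authors had normalized to transcript length and library size before deposit, read here as FPKM. The header names no unit, and FPKM was inferred because the values are not whole and their smallest nonzero values fall as transcripts get longer; TPM cannot be excluded. Every row of the deposited table has a value of at least 1 in at least 2 libraries, as a filter on low values would leave it. Read depth is unknown, and no interval that needs it is given. Isoform shares of single reads enter the values, so whole reads could not be recovered. The reference held here has another build than the authors', so no coordinates are printed, and genes are named by symbol and Ensembl gene identifier as the table pairs them. Of 17 genes without a symbol, 15 were named through their identifier. The 8 genes whose values equal those of another gene in every library are not named.

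The 13299 transcripts were summed to 9636 genes, 2619 of which had more than 1 listed transcript. Genes with a mean of at least 1 FPKM in at least 1 group were tested, 9561 in all, and 75 were left out. Groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, all 9 libraries in 1 fit with 6 residual degrees of freedom, and Benjamini-Hochberg adjustment over all tested genes at 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. The groups come from the labels; nothing says that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. A total of 25 gene lists was fixed before the data were examined: Wnt targets, EWS/ETS-activated and EWS/ETS-repressed genes, matrix, TGF-beta response, adhesion and cytoskeleton, migration, neural crest and neuronal, mesenchymal, posterior HOX, S phase and mitosis, sterol synthesis, unfolded protein and amino acid stress, interferon response, p53, hypoxia and glycolysis, immediate early and heat shock, mitochondrial transcripts, ribosomal proteins, replication-dependent histones, housekeeping, and markers of fibroblasts, endothelial, blood and epithelial cells. The deposited table did not hold every listed gene, and list members are counted among those tested. Tested were 16 of 34 Wnt targets, 23 of 44 matrix, 12 of 32 interferon response and 7 of 29 mesenchymal genes. For S phase and mitosis it was 32 of 33. The 21 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01. The tests were two-sided and adjusted over the lists, and were repeated with an estimated correlation and with fry. Fry tests whether a list moves one way on balance and does not compare it with other genes. Estimating the correlation can end a call even where the estimate is not above 0.01. The migration list with WNT3A had an estimate of 0.00911, and its unadjusted camera p went from 0.0132 to 0.0469. A call lost in this way therefore does not by itself show that the members are correlated. Genes to be named were chosen by a rule fixed with the lists: AXIN2, LEF1, NKD1 and TCF7 whatever their values; the 10 highest and 10 lowest log2 fold changes against the control among genes past the test whose groups do not overlap and whose higher mean is at least 5 FPKM (5 and 5 for the direct comparison); and up to 4 members of each list with the smallest p (2 for the direct comparison). Simulated data had the means and spread of the 9561 genes and 200 changed ones, with equal numbers changed by 1 and by 2 on the log2 scale. The changed genes were drawn from those with a control mean above 1 on the log2(FPKM + 1) scale. The gene test recovered 63%, 57% and 73% of changes of 1 and 96%, 92% and 95% of changes of 2. The order is WNT3A against control, WNT3A with RSPO against control and WNT3A with RSPO against WNT3A. False calls made up 8.09%, 3.25% and 6.15% of the calls. Fewer changed genes make the adjusted threshold stricter, so these shares do not hold for a comparison with few changes or for genes low in the control. Camera called the shifted list in each of the 3 simulations and 0 of 20 unshifted lists; simulated genes were independent of each other.

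Alternatives were other pseudocounts (0.1 and 5), no filter and a mean of at least 5, no trend, each pair of groups alone, median-of-ratios scaling, the replicate number as a block, a fold threshold, a stricter threshold for shared genes, and leaving out each library; quantile normalization, transcripts tested singly and leaving out 2 libraries together were added after the data were seen. Some genes chosen by the rule are not reported here. Figures were drawn with matplotlib 3.10.9.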

Results

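Gene expression was measured by RNA sequencing in 9 libraries of total RNA from CHLA25, an Ewing sarcoma cell line, made to carry the 7TGP reporter, which produces a fluorescent protein when Wnt/beta-catenin signalling is active. Ewing sarcoma is a tumour of bone and soft tissue driven by a fusion of EWS with an ETS transcription factor. Cells had been kept for 48 h in medium mixed 1:1 with conditioned medium, with or without R-spondin 2 (RSPO), a secreted protein that strengthens the response to Wnt ligands. The 3 groups held 3 libraries each: a control with medium conditioned by L cells, the cells in the top 10% after WNT3A, and the cells in the top 10% after WNT3A with RSPO. The labels do not say whether control cells were sorted, so in both comparisons with the control the ligand and the selection of the brightest cells changed together. The deposited table listed FPKM for 13299 transcripts, which were summed to 9636 genes, of which 9561 were tested. Read depth is unknown, because the values are normalized and whole reads could not be recovered from them; the listed FPKM summed to between 214408 and 261942 per library. Spearman correlations of gene values ranged from 0.940 to 0.964 within groups and from 0.914 to 0.965 between groups. The first principal component, with 29.8% of the variance, put the controls between -32.4 and -16.6 and the 6 treated libraries between 7.77 and 18.4. Control replicate 3 was the control nearest the treated libraries on it, and libraries of the treated groups lay apart from their own group on the next 2 components. WNT3A replicate 1 was at 21.1 on the second, WNT3A replicate 2 at 22.5 on the third, and WNT3A with RSPO replicate 3 at -24.4 and -20.0.

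The first comparison asks what differs in cells that responded most to WNT3A. Wnt target genes were higher in the top 10% of WNT3A-treated cells than in the control. LEF1 (ENSG00000138795), a transcription factor that works with beta-catenin, rose from 1.14 ± 0.169 to 9.60 ± 0.934 FPKM (SD, n = 3), a log2 fold change of 2.31 ± 0.12 (SE) with an adjusted p of 0.000166 by limma. NKD1 (ENSG00000140807), a feedback inhibitor of the pathway, rose from 0.788 ± 0.303 to 3.80 ± 0.235 FPKM (adjusted p = 0.0112). GAD1 and FZD7, a Wnt receptor, also rose, by log2 1.39 and 0.74. TCF7, a partner of beta-catenin, was at 0.372, 0.983 and 0 FPKM in the control libraries and at 2.31 ± 0.0880 FPKM with WNT3A (adjusted p = 0.0414). AXIN2 (ENSG00000168646), a feedback gene of the pathway, had 2.68 ± 0.276 FPKM in the control and 4.96 ± 1.25 FPKM with WNT3A and did not pass the test (adjusted p = 0.110). Of the 16 tested Wnt targets, 5 rose, 0 fell and 11 did not pass; adjusted over the list alone, 9 rose. The list stood above the other genes by camera (adjusted p = 1.22e-07, median log2 fold change 0.61), and this held with an estimated correlation (adjusted p = 0.0332).

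Genes of S phase and mitosis were lower in the WNT3A group. The proliferation marker MKI67 fell from 36.1 ± 2.38 to 16.0 ± 0.739 FPKM (adjusted p = 0.00505), CDK1, the mitotic kinase, from 93.8 ± 3.33 to 45.0 ± 3.75 FPKM (adjusted p = 0.00505), and CCNA2, a cyclin, from 40.3 ± 4.29 to 19.3 ± 1.40 FPKM (adjusted p = 0.00636). PLK1, a kinase of mitosis, fell by 1.05 on the log2 scale, and BUB1B, a checkpoint gene, by 1.46. Of 32 tested members, 17 fell and 0 rose, and 27 fell adjusted over the list alone. The median log2 fold change was -0.78 (camera, adjusted p = 2.63e-16). The list did not pass with an estimated correlation (adjusted p = 0.0802) and passed by fry (adjusted p = 0.000421). Among the genes of sterol synthesis, 3 of 22 fell, among them FDPS (log2 fold change -0.75) and HSD17B7 (-1.11), and 6 fell adjusted over the list alone. The list median was -0.61 (camera, adjusted p = 0.000274; adjusted p = 0.281 with an estimated correlation). In the hypoxia and glycolysis list, 2 of 18 fell, the glycolytic enzymes TPI1 (-0.61) and PGK1 (-0.60), with 8 lower and 2 higher adjusted over the list alone (camera, adjusted p = 0.0194; adjusted p = 0.281 with an estimated correlation). The genes that every cell uses moved in the same direction as these lists: 2 of 15 fell, PGK1 and HPRT1, and 5 adjusted over the list alone (camera, adjusted p = 0.0194; adjusted p = 0.281 with an estimated correlation).

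Genes reported to be activated by EWS/ETS fusions were lower and those reported to be repressed by them were higher, each in few members. Of 33 tested activated genes, 5 fell, among them LOXHD1 (log2 fold change -1.21), AURKA (-0.89), MYBL2 (-0.79) and FOXM1 (-0.76), and 0 rose. Adjusted over the list alone, 9 fell and 2 rose (camera, adjusted p = 0.0194; adjusted p = 0.281 with an estimated correlation). AURKA and FOXM1 are among the 3 tested genes that this list shares with the S phase and mitosis list. Of 26 tested repressed genes, 2 rose, IGFBP5, which binds insulin-like growth factors, from 21.2 ± 0.228 to 48.9 ± 6.85 FPKM (adjusted p = 0.0104), and CYR61, a matricellular protein (log2 fold change 1.45), while 1 fell, TIMP3 (-1.11), an inhibitor of matrix metalloproteinases. Adjusted over the list alone, 5 of the 26 rose and 1 fell (camera, adjusted p = 0.000274; adjusted p = 0.281 with an estimated correlation). Among the 17 tested genes of the TGF-beta response, 3 rose, ID1 (log2 fold change 0.74), ID3 (0.52) and CYR61, and 0 fell; adjusted over the list alone, 4 rose and 1 fell (camera, adjusted p = 0.0139; adjusted p = 0.281 with an estimated correlation). Of 26 adhesion and cytoskeleton genes, CNN2 (1.10) and VIM (0.70), which code for actin-binding and intermediate filament proteins, rose and S100A10 (-0.92) fell, as many as adjusted over the list alone (camera, adjusted p = 0.0134; adjusted p = 0.281 with an estimated correlation). Of 23 matrix genes, 1 rose, COL6A2 (0.73), and 2 fell, TIMP3 and LOXL2 (-0.65); adjusted over the list alone, 5 rose and 3 fell (camera, adjusted p = 0.0150; adjusted p = 0.281 with an estimated correlation). Of 19 migration genes, 1 rose, the chemokine CXCL12 (0.98), and 3 adjusted over the list alone (camera, adjusted p = 0.0199; adjusted p = 0.281 with an estimated correlation). Immediate early and heat shock genes, which can rise when cells are dissociated and sorted, moved with these groups: 1 of 21 rose, KLF2 (0.76), also the only one adjusted over the list alone (camera, adjusted p = 0.0150; adjusted p = 0.281 with an estimated correlation).

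**Figure D1:**
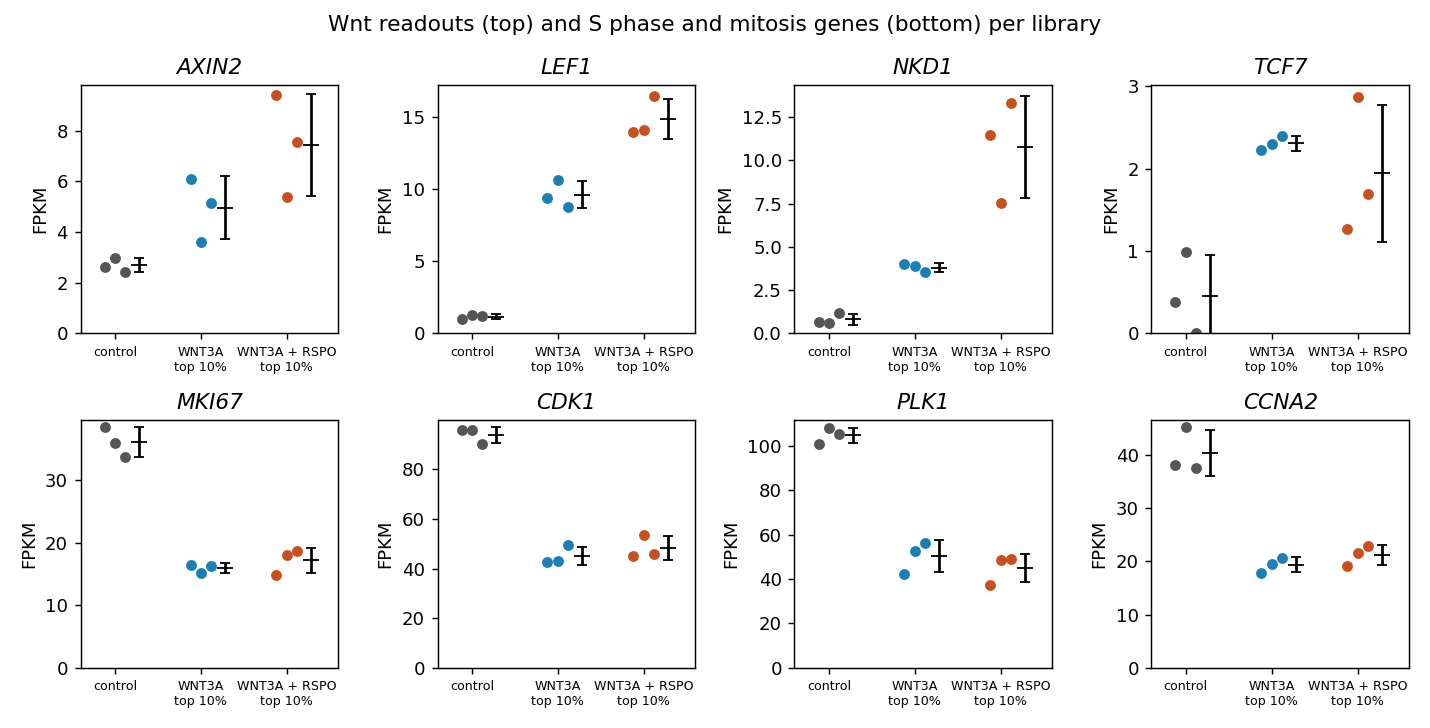
FPKM of 4 Wnt readouts and 4 S phase and mitosis genes in each of the 9 libraries (points), with the mean and SD of each group of 3 (bars, ending at 0 where the SD reaches below it). LEF1 averaged 1.14, 9.60 and 14.9 FPKM in the control, WNT3A and WNT3A with RSPO groups, and MKI67 36.1, 16.0 and 17.2 FPKM.

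Over all genes, 422 differed between the WNT3A group and the control, 128 higher and 294 lower (limma, adjusted p under 0.05), and 111 of them by at least 1 on the log2 scale, 55 higher and 56 lower. After median-of-ratios scaling the count was 381 with 197 higher and 184 lower, and after quantile normalization 167 were higher and 214 lower, so the excess of lower genes depends on the scale of the libraries. The 3 libraries of each group did not overlap in 28.2% of tested genes, where chance gives 10%. Among the largest changes, DIO3, an enzyme that inactivates thyroid hormone, rose from 1.21 ± 0.205 to 39.9 ± 20.4 FPKM (adjusted p = 0.00564). PHLDB2 (log2 fold change 1.70), WFDC1 (1.64), HEY1 (1.60), a Notch target, TFPI2 (1.88) and C8orf4 (1.83) were also higher. SULT1E1 (-1.52), an estrogen sulfotransferase, NMB (-1.49), a neuropeptide, and ASPM (-1.30), a spindle gene, were lower. The count fell to 82 and 60 without control replicate 1 and 2, to 98, 179 and 132 without WNT3A replicate 1, 2 and 3, and to 269 without WNT3A with RSPO replicate 1. It was 189 with only these 2 groups in the fit and 145 genes when transcripts were tested singly. Of the 45 printed genes that the naming rule chose for this comparison and that passed, 10 also passed whichever library was left out (CCNA2, CDK1, DIO3, GAD1, IGFBP5, LEF1, MKI67, PHLDB2, PLK1 and S100A10). Without WNT3A replicate 3, 9 of the 15 lists past the threshold remained; those of EWS/ETS-activated, matrix, migration, posterior HOX, glycolysis and housekeeping genes did not (adjusted p = 0.137, 0.0546, 0.0546, 0.125, 0.0546 and 0.0552). The medians of the first 4 went from -0.36, 0.41, 0.07 and 0.14 to -0.17, 0.17, 0.10 and 0.07. Without WNT3A replicate 2 the matrix median was 0.22. The migration median was 0.20 without control replicate 3, 0.12 and 0.14 without WNT3A replicate 1 and 2, and 0.19 and 0.14 after median-of-ratios scaling and quantile normalization. The TGF-beta and adhesion medians, 0.11 and 0.06, ranged from 0.02 to 0.22 and from 0.03 to 0.12 with 1 library left out. They were 0.18 and 0.15 after median-of-ratios scaling and 0.18 and 0.11 after quantile normalization. Glycolysis was also lost without control replicate 3 (0.0635), housekeeping without control replicate 2 (0.0886), and immediate early genes without control replicate 3 (0.0522) or WNT3A replicate 2 (0.115, median 0.14 against 0.33).

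In the comparison of WNT3A with RSPO against the control, Wnt target genes were again higher than in the control. LEF1 was at 14.9 ± 1.39 FPKM, a log2 fold change of 2.89 ± 0.12 (SE; adjusted p = 1.96e-05 by limma), and NKD1 at 10.8 ± 2.95 FPKM (log2 fold change 2.70, adjusted p = 0.000675). AXIN2 rose to 7.45 ± 2.02 FPKM (adjusted p = 0.0177, and up to 0.0583 with 1 library left out), while TCF7, at 1.94 ± 0.831 FPKM, did not pass (adjusted p = 0.0615). GAD1 (log2 fold change 2.09) and FZD7 (0.85) rose as well. Of the 16 Wnt targets, 7 rose, 0 fell and 9 did not pass, and 10 rose adjusted over the list alone (camera, adjusted p = 2.69e-11; adjusted p = 0.0113 with an estimated correlation). The median of the Wnt targets was 0.73, and 1.21 with a pseudocount of 0.1. Of 32 S phase and mitosis genes, 17 fell, 0 rose and 25 fell adjusted over the list alone, with a median of -0.75. MKI67 was at 17.2 ± 2.03 FPKM, CDK1 at 48.2 ± 4.76 and PLK1 at 45.0 ± 6.44, with adjusted p-values of 0.00290, 0.00290 and 0.00367, and KIF11, a mitotic motor, fell by 0.89 on the log2 scale. This list passed by camera (adjusted p = 2.63e-14) and by fry (adjusted p = 0.000480), and did not with an estimated correlation (adjusted p = 0.108).

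Among the 33 genes reported as EWS/ETS-activated, 6 fell and 2 rose. LOXHD1 fell from 7.60 ± 0.436 to 0.506 ± 0.439 FPKM (adjusted p = 0.00103), and FOXM1 (log2 fold change -0.87) and MYBL2 (-0.80) fell. FOXM1 is also on the S phase and mitosis list, which fell as well. Adjusted over the list alone, 9 fell and 2 rose (camera, adjusted p = 0.00407; adjusted p = 0.287 with an estimated correlation). Of the 26 reported as repressed, 6 rose and 1 fell, and 9 rose and 1 fell adjusted over the list alone. TNC, a matrix glycoprotein, rose from 0.451 ± 0.318 to 5.51 ± 2.77 FPKM (adjusted p = 0.00851), MMP2, a matrix protease, from 14.6 ± 2.12 to 33.0 ± 7.61 FPKM (adjusted p = 0.0149), and IGFBP5 to 52.8 ± 10.6 FPKM (adjusted p = 0.00499), while TIMP3 fell from 323 ± 23.7 to 121 ± 32.3 FPKM (adjusted p = 0.00795). This list passed by camera (adjusted p = 2.70e-05; adjusted p = 0.220 with an estimated correlation). Of 23 matrix genes, which share 11 members with it, 3 rose, TNC, MMP2 and COL6A2 (log2 fold change 1.01), and 3 fell, TIMP3 among them; adjusted over the list alone, 5 rose and 3 fell (camera, adjusted p = 0.0154; adjusted p = 0.287 with an estimated correlation). Of 17 TGF-beta response genes, TGFB2 (1.53), the ligand itself, CYR61 (1.65) and ID1 (0.50) rose and BHLHE40 (-0.72) fell; adjusted over the list alone, 4 rose and 1 fell (camera, adjusted p = 0.0112; adjusted p = 0.288 with an estimated correlation). Of 26 adhesion and cytoskeleton genes, 3 rose, CNN2 (1.07), VIM (0.86) and CALD1 (0.89), and 1 fell, S100A10 (-1.33), with 5 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.0211; adjusted p = 0.288 with an estimated correlation). Of 19 migration genes, 3 rose, TNC, CXCL12 (0.90) and TWIST1, a transcription factor of mesenchymal cells (0.79), and 4 adjusted over the list alone (camera, adjusted p = 0.0154; adjusted p = 0.220 with an estimated correlation).

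Sterol synthesis genes were lower with WNT3A and RSPO as well: 4 of 22 fell, among them FDPS (log2 fold change -0.91), ACAT2 (-0.93) and STARD4 (-0.77), and 9 adjusted over the list alone (camera, adjusted p = 0.000310; adjusted p = 0.315 with an estimated correlation). In the hypoxia and glycolysis list, 5 of 18 fell, among them LDHA (-0.83), ENO1 (-0.63), TPI1 (-0.67) and PGK1 (-0.57), with 10 lower and 2 higher adjusted over the list alone (camera, adjusted p = 0.0211; adjusted p = 0.288 with an estimated correlation). Housekeeping genes moved with them, 4 of 15 lower, HPRT1 (-0.75), TUBB (-0.67), PPIA (-0.53) and PGK1, also 4 adjusted over the list alone (camera, adjusted p = 0.0192; adjusted p = 0.288 with an estimated correlation). Of the 21 immediate early and heat shock genes, 1 rose, KLF2 (0.75), also adjusted over the list alone (camera, adjusted p = 0.00407; adjusted p = 0.287 with an estimated correlation).

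**Figure D2:**
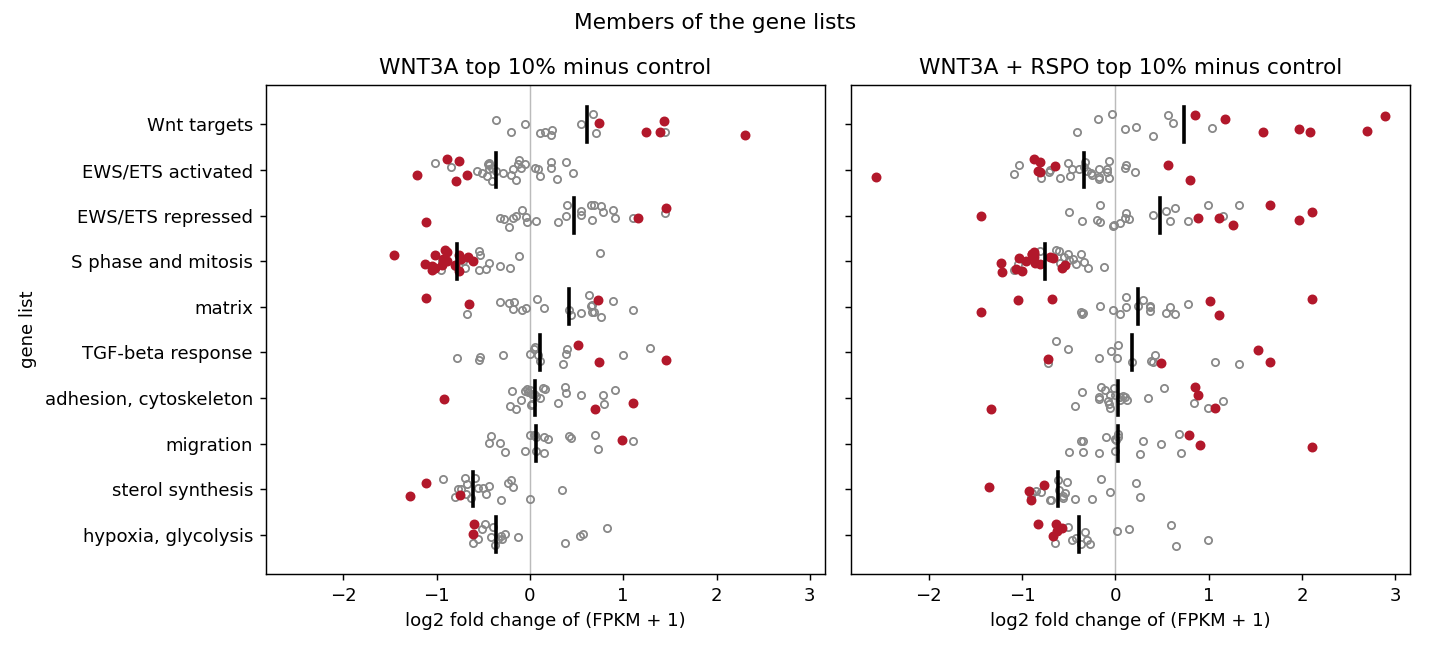
Log2 fold changes of (FPKM + 1) of the tested members of 10 gene lists against the control (points, red where adjusted p was under 0.05, limma), with the list median (black bar). The S phase and mitosis list had medians of -0.78 and -0.75 and the Wnt targets 0.61 and 0.73.

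In total 568 genes differed between WNT3A with RSPO and the control, 175 higher and 393 lower (limma, adjusted p under 0.05), and 149 by at least 1 on the log2 scale, 81 higher and 68 lower. After median-of-ratios scaling there were 516, 279 higher and 237 lower, and after quantile normalization 272 were higher and 258 lower. The groups did not overlap in 29.5% of tested genes, against 10% by chance. DIO3 reached 84.0 ± 29.1 FPKM (log2 fold change 5.20, adjusted p = 0.00101). CRHBP (2.56), which binds corticotropin-releasing hormone, TFPI2 (2.67), WFDC1 (2.44), HEY1 (2.27), PHLDB2 (2.22) and ACSM3 (2.21) were higher. STC1 (-2.38), a secreted glycoprotein, SULT1E1 (0.628 ± 0.291 FPKM, against 5.69 ± 2.25 FPKM in the control), HR (-1.76) and CPVL (-1.69) were lower. The count fell to 238 and 140 without control replicate 1 and 2 and to 218, 329 and 321 without WNT3A with RSPO replicate 1, 2 and 3; without control replicate 3 and WNT3A with RSPO replicate 3 together it was 297. It was 288 with only these 2 groups in the fit and 238 genes when transcripts were tested singly. Of the 56 printed genes that the naming rule chose for this comparison and that passed, 29 also passed whichever library was left out. The other 27, each lost without at least 1 library, were ACAT2, AXIN2, BHLHE40, BMP2, CALD1, COL6A2, CPVL, CXCL12, CYR61, ENO1, HIST2H2AC, HPRT1, ID1, IFIT1, KLF2, LDHA, MMP2, MYBL2, PGK1, PPIA, RPSA, STARD4, TFPI2, TPI1, TUBB, TUBB3 and VIM. PGK1 was lost in each of the 9 omissions, and BHLHE40, CXCL12, PPIA and STARD4 in 8. The medians of the migration and adhesion lists were near 0, at 0.03 each, and their sign rested on single libraries. The migration median was -0.01 and -0.02 without control replicate 1 and 2 and 0.23 without control replicate 3, and the adhesion median was -0.01 without control replicate 2 or WNT3A with RSPO replicate 1. After median-of-ratios scaling they were 0.12 and 0.11, and after quantile normalization 0.12 and 0.13. Among lists, adhesion was lost without control replicate 2 (adjusted p = 0.0503) or WNT3A with RSPO replicate 1 (0.0534), housekeeping without control replicate 2 (0.0861) and glycolysis without control replicate 3 (0.0598). Without the 2 libraries together, EWS/ETS-activated, matrix, housekeeping (0.0508 each) and glycolysis genes (0.0536) did not pass.

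The direct comparison of WNT3A with RSPO against WNT3A alone, both top 10% groups, asks how the groups differ where RSPO was added. Each top 10% was taken after its own treatment, so the reporter level of the selected cells may have changed together with RSPO. The Wnt target list was higher with RSPO (camera, adjusted p = 2.44e-06, median log2 fold change 0.17, 13 of 16 members above 0). Its adjusted p was 0.0545 by camera with an estimated correlation and 0.0116 by fry. Without WNT3A replicate 3 the median was 0.30. No single gene passed: limma called 0 of 9561 at an adjusted p under 0.05, 0 also without the trend, and 355 had an unadjusted p under 0.05. The smallest adjusted p was 0.403. The genes that shared it included NKD1 (log2 difference 1.26 ± 0.20 SE, 3.80 ± 0.235 against 10.8 ± 2.95 FPKM) and LOXHD1 (-1.35 ± 0.22 SE, 2.71 ± 0.288 against 0.506 ± 0.439 FPKM). LEF1 differed by 0.58, AXIN2 by 0.50, TNC by 1.01, TWIST1 by 0.60, POU4F1 by 0.69 and TCF7 by -0.20, each with an adjusted p of 0.999. Adjusted over the list alone, 4 of the 16 Wnt targets were higher and 0 lower. The 3 libraries of each group did not overlap in 8.73% of genes, against 10% by chance. The ribosomal protein genes had a median of -0.21, with 27 of 30 below 0 and 1 lower adjusted over the list alone, RPSA (camera, adjusted p = 1.67e-07; adjusted p = 0.485 with an estimated correlation); without WNT3A with RSPO replicate 3 the median was -0.11 (adjusted p = 0.0105), and it was -0.19 after median-of-ratios scaling (adjusted p = 1.89e-07) and -0.09 after quantile normalization (adjusted p = 0.000779). The interferon response genes, 12 tested with a median of -0.24 and 0 past the test over the list alone, passed by camera (adjusted p = 0.0397; adjusted p = 0.391 with an estimated correlation). The interferon call was lost without control replicate 1 or 3, WNT3A replicate 1 or 3, or WNT3A with RSPO replicate 2 or 3 (adjusted p from 0.0573 to 0.338), with a median of -0.16 in the last case. S phase and mitosis genes had a median of 0.06 and did not pass (adjusted p = 0.399).

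The comparisons with the control shared 316 called genes in the same direction, 97 higher and 219 lower, and 0 in opposite directions; 106 were called only in the comparison of WNT3A with the control and 252 only in that of WNT3A with RSPO. The shared count was 71 and 52 without control replicate 1 and 2, 85, 157 and 121 without WNT3A replicate 1, 2 and 3, 149 and 184 without WNT3A with RSPO replicate 1 and 2, and 28 at an adjusted p under 0.01. Independent lists of these sizes would share 2.34 higher and 12.1 lower genes. In 100 simulated pairs of unchanged groups against the same controls, 0.01 higher and 0 lower were shared on average. With no gene changed and genes drawn independently, hardly any gene passes there. The simulated count therefore cannot show how many shared calls the common controls add. The log2 fold changes correlated across genes with a Pearson r of 0.803, against 0.50 in the simulation, and genes are not independent replicates; the covariance was 0.134 against 0.0359 simulated, a difference of 0.0980. The 3 controls cannot be split into 2 sets of at least 2, so part of the excess may come from the shared controls. Of the 97 genes higher in both, 65 had the larger fold with RSPO, and of the 219 lower in both, 113 had the larger fall, a difference that was not tested gene by gene beyond the direct comparison.

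**Figure D3:**
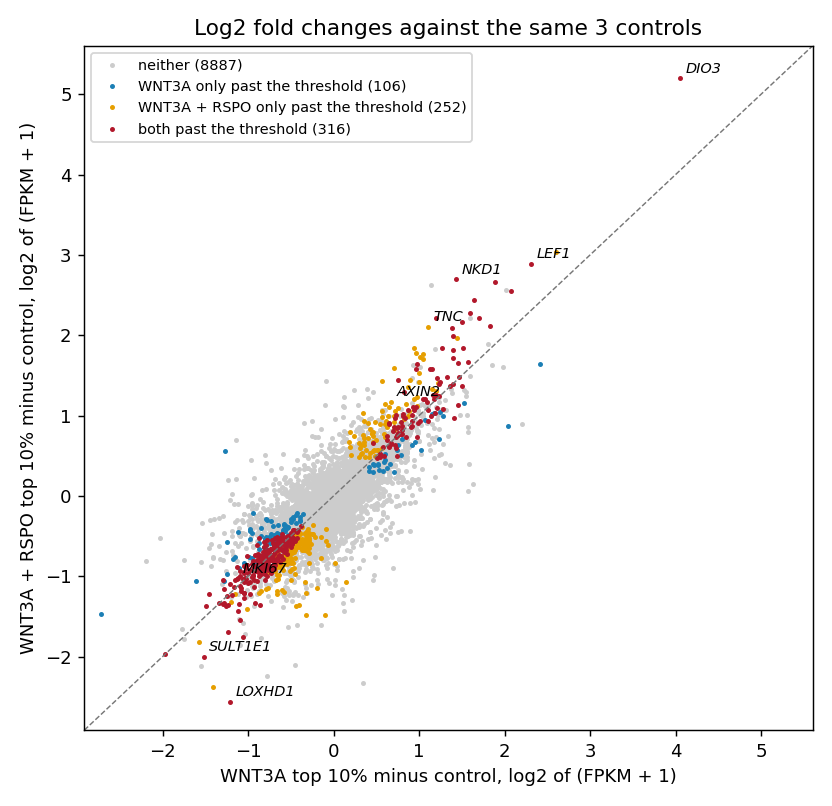
Log2 fold changes of (FPKM + 1) of the 9561 tested genes against the same 3 controls, WNT3A on the horizontal and WNT3A with RSPO on the vertical axis, coloured by which comparison passed an adjusted p of 0.05. The 316 genes past it in both lie on the same side of 0 on both axes.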

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

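Quantile normalization, the test of single transcripts, the omission of 2 libraries together, both scalings for the lists and omissions for the shared genes were chosen after the data were seen. The counts of changed genes stayed within 1.5 times their value (422, 568 and 0) under both other pseudocounts, both other filters and no trend. They also did under both scalings and the block, with the split changed by scaling as given in the report. The genes called were not all the same. The block kept 298 of the 422 and 470 of the 568, median-of-ratios scaling 312 and 412, and quantile normalization 314 and 425. Without control replicate 3, 289 and 394 were kept. With only the groups compared in the fit, 189 and 288 genes were called against the control, where 3 fewer libraries estimate the spread; a log2 fold change of at least 1 left 111 and 149. Single transcripts gave genes in number 145, 238 and 0; the cause was not tested. Leaving out 1 library gave 60 to 440 genes with WNT3A, 140 to 550 with WNT3A and RSPO, and 0 to 0 in the direct comparison. Without control replicate 3 and WNT3A with RSPO replicate 3, 444, 297 and 1 were called, the last being PARL, lower with RSPO and chosen after its values were seen (11.2 ± 0.791 with WNT3A and 3.71 ± 2.74 FPKM with RSPO, over all 3 libraries each). The lists past the threshold numbered 15, 14 and 3 by camera. With an estimated correlation there were 1, 1 and 0, the Wnt targets in both comparisons with the control. Fry gave 3, 8 and 2. With WNT3A these were the Wnt target, S phase and mitosis, and glycolysis lists. With WNT3A and RSPO fry called those 3 and both EWS/ETS lists, mesenchymal, interferon response and housekeeping genes. In the direct comparison it called Wnt targets and mesenchymal genes. Camera compares a list with other genes and fry does not. Omissions gave 9 to 15, 12 to 15 and 2 to 4 lists, and the omission of both libraries 9 in the comparison of WNT3A and RSPO with the control. At an adjusted p under 0.01, 28 genes were shared by the comparisons with the control instead of 316, and omissions gave 52 to 337.

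With the replicate number as a block, 371, 586 and 0 genes, 15, 14 and 3 lists and 298 shared genes were called. Whether the numbers pair the samples stays open and was not tested. Deviations from the group means correlated between -0.0292 and 0.204 for equal numbers, 3 of 9 pairs above 0.1. For different numbers they correlated between -0.270 and 0.214, a range that overlaps. In 2 of 9 samples the correlation was highest with its own number in both other groups.

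For the named genes, 2145 of 2581 single results kept direction and side of the threshold, 416 lost the call, 20 gained it and 0 changed sign. The total includes results of genes not called at first, which could not lose a call, among them all 356 of the direct comparison. Of the lost calls, 234 were in the comparison of WNT3A with the control and 182 in that of WNT3A with RSPO. Depth is unknown, so what it limits cannot be stated; the median SE of a log2 difference was 0.17.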

Other observations

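Stress genes of unfolded proteins and amino acids were higher as a list in both comparisons with the control (23 tested, medians 0.35 and 0.46; camera, adjusted p = 0.00458 and 0.000272; adjusted p = 0.281 and 0.287 with an estimated correlation), with 0 members past the test, over all genes or adjusted over the list alone. The medians depended on the controls: without control replicate 1, 2 or 3 the first was 0.20, 0.23 or 0.58, and without control replicate 1 or 2 the other was 0.27 or 0.30. Without control replicate 3 and WNT3A with RSPO replicate 3 together, the median with WNT3A and RSPO was 0.70. ASNS, which makes asparagine, went from 46.9 ± 34.5 to 102 ± 26.0 and 92.6 ± 8.75 FPKM (adjusted p = 0.108 and 0.115). GADD45A, a p53 target, rose from 15.2 ± 3.23 to 42.1 ± 12.1 and 62.9 ± 7.10 FPKM (adjusted p = 0.0148 and 0.00301) and FAS fell with WNT3A (log2 fold change -0.98), while the p53 list, 14 tested, did not pass (adjusted p = 0.204 and 0.158; 1 higher and 1 lower, then 1 higher and 0 lower, also adjusted over the list alone). Neuronal genes did not pass as a list (13 tested, adjusted p = 0.770 and 0.459), but POU4F1, a transcription factor of sensory neurons, rose from 68.4 ± 11.1 to 116 ± 24.2 and 187 ± 23.9 FPKM (adjusted p = 0.0491 and 0.00499), and TUBB3, a neuronal tubulin, rose with WNT3A and RSPO (log2 fold change 1.03); adjusted over the list alone, 1 and 2 rose. Of 7 mesenchymal genes, BMP2 rose in both (0.79 and 0.92) and TWIST1 with WNT3A and RSPO, where the list passed (adjusted p = 0.220 and 0.0284; adjusted p = 0.281 and 0.220 with an estimated correlation); adjusted over the list alone, 1 rose, then 2 rose and 1 fell. The list median was 0.42, and 0.49 after median-of-ratios scaling and 0.50 after quantile normalization, where the adjusted p was 0.0536 and 0.0506 and the call ended. The call was also lost without control replicate 3 (0.0547) or WNT3A with RSPO replicate 2 (0.0572), and without control replicate 3 and WNT3A with RSPO replicate 3 together (0.0736).

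Posterior HOX genes, 10 tested with 0 past the test over all genes or the list alone, had medians of 0.14 and 0.07 (camera, adjusted p = 0.0331 and 0.0902; adjusted p = 0.281 and 0.287 with an estimated correlation). Without WNT3A replicate 3 the first median was 0.07, and after median-of-ratios scaling 0.22. Ribosomal protein genes had a median of 0.22 with WNT3A (camera, adjusted p = 0.000347; adjusted p = 0.281 with an estimated correlation; 0 past over the list alone), 0.32 after median-of-ratios scaling (adjusted p = 0.000298), 0.09 after quantile normalization, where the call ended (adjusted p = 0.0754), and -0.04 with WNT3A and RSPO (adjusted p = 0.630), where RPSA fell, also adjusted over the list alone. By fry, the interferon response genes were lower with WNT3A and RSPO (adjusted p = 0.0263, 9 of 12 members below 0) and did not pass with WNT3A (adjusted p = 0.370). By camera they did not pass against the control (adjusted p = 0.756 and 0.366). IFIT1 was lower with WNT3A and RSPO (log2 fold change -0.80), also the only one adjusted over the list alone. The 12 replication-dependent histone genes did not pass by camera either (adjusted p = 0.802 and 0.558). HIST1H2BD rose with WNT3A and HIST2H2AC fell with WNT3A and RSPO. Adjusted over the list alone, 2 histone genes rose, then 2 rose and 1 fell. Nor did the 6 fibroblast markers pass by camera (adjusted p = 0.139 and 0.30, 0 past over the list alone). Too few were tested among markers of endothelial (3), blood (2) and epithelial cells (1), and mitochondrial transcripts numbered 0. The 1 epithelial marker was lower in both comparisons with the control (log2 fold change -0.79 and -1.09). It passed over the list alone, where nothing is adjusted for, and not over all genes. ERG, an ETS gene on the endothelial list, had 17.7 ± 1.10, 16.2 ± 0.355 and 16.0 ± 0.70 FPKM. In the comparisons with the control, the test and the median differed in sign for neuronal, mesenchymal and interferon genes with WNT3A and for neuronal and ribosomal protein genes with WNT3A and RSPO, none of which passed. Between the treated groups the median, mean or test differed in sign for matrix, TGF-beta, migration, neuronal, S phase and mitosis, stress and housekeeping genes, none of which passed.

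For the patterns weighed here, the tests of scaling, of left-out libraries and of a graded fall were chosen after the results were seen. S phase and mitosis genes were lower in both top 10% groups. After median-of-ratios scaling the list medians were -0.69 (95% bootstrap interval over members -0.83 to -0.58) and -0.65, and after quantile normalization -0.71 and -0.66. The median of all genes was only -0.08 and -0.10 before scaling, so median-of-ratios scaling could move the list little whatever the cause. That test therefore decides little, though a shift common to all genes was far smaller than the list medians. Of 10000 random lists matched on expression and transcript length, 0% had medians as low in either comparison, which argues against length or expression as the cause. A fall graded with Wnt activity stays open: between the treated groups the median log2 difference was 0.0619 (interval -0.04 to 0.09). That the selection of bright cells rather than WNT3A lowers these genes cannot be told apart from an effect of the ligand, because the design changes both. The list's camera call does not hold with an estimated correlation. By fry, which does not compare it with other genes, the list was lower in both comparisons (adjusted p = 0.000421 and 0.000480).

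As a list, ribosomal protein genes were lower with RSPO than with WNT3A alone by camera, a call lost with an estimated correlation (adjusted p = 0.485), and 0 of 30 passed over all genes. Scaling stays open: after quantile normalization the median went from -0.21 to -0.0868 (95% interval -0.14 to -0.01), while median-of-ratios scaling left it at -0.19. Whether 1 library decides stays open too, since without WNT3A with RSPO replicate 3 the median was -0.11 (interval -0.15 to -0.03). The interval draws members and does not measure the spread between libraries. By camera at the preset correlation, the measure used for the Wnt targets, the list still passed without that library (adjusted p = 0.0105). Length and expression stay open: the list was at percentile 0.35 of 10000 matched lists, below the bound of 1 written in advance, but the genes drawn had a median of 6.92 on the log2 scale against 9.02 for the members, so the match failed, a condition added after the percentile was seen because the bound assumed a full match, and their lists already had a median of -0.14. RSPO itself remains an untested explanation.

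Wnt targets were higher with RSPO than with WNT3A alone. By camera at the preset correlation the call did not rest on 1 treated library, as the highest adjusted p after leaving out 1 was 0.000237. The omissions were not run with an estimated correlation, so they do not settle this beyond the preset test. The list was at percentile 99.8 (15 of 16 members with a length) of lists matched on length and expression. The hypothesis that all genes rising with WNT3A rise further with RSPO was tested on 272 genes higher in the pooled treated groups, without the Wnt list. Their median was 0.04 (95% interval 0.01 to 0.07), against -0.02 for all genes, and 60.3% were above 0. Camera at the preset correlation placed them higher (p = 4.10e-06). Camera with an estimated correlation, the test set in advance, gave p = 0.190, so this stays open. The mean of these genes differed with p = 0.2 in an exact two-sided permutation test, which cannot go below 0.1. Of the 608 genes lower in the pooled treated groups, 43.4% were above 0, with a median of -0.02 (camera at the preset correlation, p = 0.361). The Wnt list itself did not pass with an estimated correlation (adjusted p = 0.0545). It passed by fry (adjusted p = 0.0116), which does not compare it with other genes.

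Other splits of the 6 libraries of each comparison number 10 with the real one, too few for a share under 0.05. With WNT3A the real split gave 422 genes and the highest other 1, so 1 of the 10 splits, the real one, gave as many; with WNT3A and RSPO these were 568 and 0 (again 1 split), and in the direct comparison 0 and 1 (all 10 splits). For lists the real split gave 15 and the highest other 10 with WNT3A (1 split as large), 14 and 9 with WNT3A and RSPO (1 split), and 3 and 9 in the direct comparison, where 4 splits gave as many. In the direct comparison another split thus called 3 times as many lists as the real one. Whether a structure of these samples beyond their groups or the preset correlation of 0.01, where estimates reached 0.486, lets camera call so many was not tested. Calls were also lost where the estimate was below 0.01, as in the migration list with WNT3A (0.00911).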
